A study of Mus musculus with 36 samples.

How the data were processed

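RNA-seq and H2A.Z ChIP-seq were made from the hippocampus of young and old C57BL/6J mice, naive or fear conditioned. Groups were taken from the labels: 12 RNA libraries and 12 immunoprecipitated libraries, 3 for each of 4 groups, and 12 input libraries that were not analysed here. Title numbers of the RNA libraries are unique, and the labels do not say whether replicates came from separate animals.

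For RNA, the authors deposited whole-number read counts per gene symbol for each library, without normalization. For H2A.Z, the authors deposited 1 table of consensus peaks on mm10, with log2 folds between groups and log2 mean levels (concentrations) per group as DiffBind gives them. The p-value and FDR columns of that table were computed and adjusted by the authors, with a scaling that is not given in the sources used here. Other columns of the authors' table give the number of libraries of a group, 0 to 3, in which a peak was called, and distances in bp to genes and to regions of 4 histone marks. Per the labels, the tools were FastQC, Trim Galore 0.4, cutadapt, Bowtie2 2.2.1, TopHat, HTSeq 0.6.1p2, MACS2 2.0.10, DiffBind 1.12.2, edgeR 3.8.6 and R 3.1.0, with the builds mm9 and mm10. Which tool and build served which assay, the gene annotation and the strand setting are not given in the sources used here.

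RNA counts were analysed in R 4.3.3 with edgeR 4.0.16, after TMM normalization and the filterByExpr filter, in 1 quasi-likelihood fit of the 4 groups. Training was tested at each age and averaged over ages, age in each condition and averaged over conditions, and the interaction as the training effect in old minus that in young mice. Benjamini-Hochberg adjustment was applied over all tested genes of a comparison at 0.05. Log2 CPM values carry a prior count of 2. Standard errors were derived from the quasi-likelihood F statistic. A gene was called separated when no library of 1 group overlapped the other. Called genes were chosen by their difference between the same libraries, so their separation is no further support for the calls.

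Of 33 fixed gene lists, 32 had enough measured members for a test. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at the estimated correlation, and with fry, adjusted over lists within a comparison. The lists cover early and later activity-regulated genes, glucocorticoid-responsive genes, interferon-response genes, inflammaging, clock and heat shock genes, synapse genes, chromatin regulators, H2A.Z and its machinery, neurogenesis, collagens, oxidative phosphorylation, ribosomal and sex-linked genes, nuclear-retained and mitochondrial RNAs, and markers of cell types and brain regions. Library scores are the mean log2 CPM of a list, compared by exact permutation of the libraries.

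H2A.Z values were described as deposited, without a test of their own, because the table holds no values per library. Folds were turned to conditioned minus naive and old minus young. The groups written T were read as conditioned by exclusion, since N was read as naive. The 4 folds close exactly around the 4 comparisons, so they share 1 scale. Levels of the old groups carry a constant offset against the folds, so levels were compared only across peaks within a group. In the deposited direction (naive minus conditioned, young minus old) it was -0.215 for training in old mice, 0.334 for age in naive and 0.118 for age in conditioned mice. The size of median folds that involve old mice therefore depends on the scale of the folds. An implied standard error was computed from each fold and its p-value. A peak within 1 kb of a transcription start site was assigned to that gene, and the strongest was used where a gene had several. Expression and H2A.Z were related across genes by Spearman correlation with 100000 permutations, and called genes by Fisher's exact test. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

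Genes were named by a rule written before the data were examined, as were the comparisons, their tests on RNA and on the joined data, the lists and the first set of other settings. Fisher's exact tests of the lists among H2A.Z promoters and the comparisons of library scores were added after the data were seen. The rule takes, per RNA comparison, the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean log2 CPM of at least 1 and separated libraries, or all that pass if fewer. It adds up to 4 members of each list with the smallest p, and always Fos, Arc, Egr1, Npas4, Junb, Nr4a1, Gfap, C4b, H2afz and H2afv. For H2A.Z it takes the 5 highest and 5 lowest folds among promoter peaks past FDR 0.05, and promoter peaks of the genes above. Outside this rule, Egr2, Malat1 and Lrrc4c, Kcnt1 in the interaction, and the H2A.Z folds of Nr4a2 and Klf10 and of Sik1 in old mice were chosen after their values were seen.

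Other settings fixed beforehand for RNA were DESeq2 1.42.0, upper-quartile factors, no filter, a mean of at least 5 CPM, limma-voom, a fit of only the 2 groups compared, and each library left out in turn. For H2A.Z they were an FDR of 0.01 and leaving out the peaks with the lowest mean levels, and for the joined data a window of 3 kb, the mean over promoter peaks and a mean of at least 5 CPM. Added after the data were seen were the choroid and nuclear RNA scores as covariates, the fit without young naive 81 and old conditioned 61, and H2A.Z counts without peaks of low mappability or at the lowest level of a group. The fit was tested on simulated data with 200 genes changed.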

Results

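The hippocampus of C57BL/6J mice was profiled at 2.5 months (young) and at 15.5 months (old) of age. At each age some mice were naive and others went through a 5 min fear conditioning session with 3 shocks of 0.5 mA lasting 2 s, and brains were frozen 30 min after training. RNA was sequenced in 12 libraries, 3 for each of the 4 groups, and the histone variant H2A.Z was mapped by chromatin immunoprecipitation in 12 libraries, again 3 per group. The 12 input libraries were not analysed here. RNA libraries held 9410843 to 13350561 counts each, and between 17017 and 17436 genes had a count in a library. Expression is given below in CPM, read counts scaled to a common library size, as mean ± SD over the 3 libraries of a group, and changes as log2 fold changes with their standard error. Libraries are named by their group and the number in their title, and the labels do not say that each came from a separate animal, so the p-values measure the spread between these samples.

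Choroid plexus transcripts and nuclear transcripts set some libraries apart before any group was compared. The mean log2 CPM of 16 markers of the choroid plexus, the ventricular tissue that secretes cerebrospinal fluid, ran from 0.53 in old conditioned library 63 to 4.98 in young naive library 81. Ttr, the transthyretin gene that this tissue expresses strongly, ran from 24.2 CPM in young conditioned library 77 to 2857 CPM in young naive library 81. By group the choroid score was 3.66 ± 1.55 in young naive, 2.82 ± 2.13 in young conditioned, 3.04 ± 1.40 in old naive and 0.93 ± 0.52 in old conditioned hippocampi (SD, n = 3 each). The difference of -2.11 between old conditioned and old naive libraries had a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries can give, and a p of 0.635 after Benjamini-Hochberg adjustment over 36 score comparisons. The score of 7 nuclear-retained RNAs, among them Malat1, Meg3 and Kcnq1ot1, was 8.27 ± 0.29 in the 6 old and 8.65 ± 0.30 in the 6 young libraries (SD; exact permutation p = 0.0519, adjusted 0.635). It ran from 7.85 in old conditioned library 61 to 9.06 in young naive library 79.

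In young mice, conditioned against naive hippocampi show which transcripts differed 30 min after training. Fosb, an AP-1 transcription factor gene, rose 2.28-fold, from 6.93 ± 0.715 to 15.7 ± 2.87 CPM (SD, n = 3 each; log2 1.19, SE 0.147, edgeR quasi-likelihood test with Benjamini-Hochberg adjusted p = 0.00492). Dusp1, coding for a phosphatase of MAP kinases, rose 2.14-fold, from 8.24 ± 1.39 to 17.5 ± 0.477 CPM (SE 0.139, edgeR adjusted p = 0.00492). Sik1, a salt-inducible kinase gene, rose 1.77-fold from 13.1 ± 0.601 to 23.1 ± 2.68 CPM (SE 0.131, edgeR adjusted p = 0.0414). The antiproliferative gene Btg2 rose 1.70-fold from 14.9 ± 1.06 to 25.3 ± 3.78 CPM (SE 0.117, edgeR adjusted p = 0.0358). These were the 4 genes that passed among 14405 tested, and 0 passed downward. At an unadjusted p under 0.05, 497 genes were higher and 458 lower. DESeq2 called 6 genes higher and 2 lower. In each of the 4 genes all conditioned libraries lay above all naive ones, as chance allows for 10% of genes and as 12.8% of all tested genes showed in one direction or the other. Genes called on these same libraries are likely to be so separated.

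Other early genes had large differences in young mice that did not pass. Fos, the best known marker gene of recently active neurons, stood at 5.14 ± 4.36 CPM in naive and 20 ± 4.96 CPM in conditioned mice (log2 2.03, SE 0.364, edgeR adjusted p = 0.10). Junb, another AP-1 gene, stood at 25.7 ± 8.30 and 51.7 ± 8.55 CPM (log2 1.02, SE 0.188, edgeR adjusted p = 0.117). Arc, whose product acts at synapses, stood at 83.8 ± 45.7 and 154 ± 14.9 CPM (log2 0.90, edgeR adjusted p = 0.730). Egr1, Nr4a1 and Npas4 had log2 differences of 0.79, 0.95 and 0.95. Young naive library 79 held 10.2 CPM of Fos, against 2.44 and 2.81 in the other 2 naive libraries, and 136 CPM of Arc against 59.9 and 55.0. Without it the log2 changes were 2.92 for Fos (edgeR adjusted p = 8.51e-05), 1.3 for Junb (0.00267) and 1.42 for Arc (0.00109). Library 79 was singled out by its values of Fos and Arc, so larger changes without it follow by construction and are no separate evidence.

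As a group, the early activity-regulated genes were higher in conditioned young mice. All 28 measured members had a positive log2 change, with a median of 0.70. 4 passed over all genes and 20 when adjusted over the list alone (camera adjusted p = 1.08e-47, with an estimated correlation adjusted p = 0.0176, fry adjusted p = 0.0342). Later effector genes had a median of 0.16, 24 of 25 positive, with 0 past over all genes and 2 past when adjusted over the list alone. The camera call is lost with an estimated correlation (adjusted p = 0.0965). Tiparp, an ADP-ribosyltransferase gene of that list, stood at 21.1 ± 0.842 and 29.8 ± 0.728 CPM (log2 0.50, edgeR adjusted p = 0.124). Glucocorticoid-responsive genes had a median of 0.24 with 5 of 18 past when adjusted over the list alone and 0 over all genes (adjusted p = 0.249 with an estimated correlation), among them Nfkbia at log2 0.57 (SE 0.144). The 17 genes of H2A.Z and its deposition machinery had a median of 0.06 and no call. H2afz itself, the main H2A.Z gene, stood at 71.9 ± 2.31 and 81.2 ± 1.35 CPM (log2 0.18, edgeR adjusted p = 0.730), and H2afv at log2 0.10. Oligodendrocyte markers had a median of -0.28, those of oligodendrocyte precursors -0.16, those of ependyma, the ciliated ventricular lining, -0.56, choroid plexus markers -0.44 and oxidative phosphorylation genes 0.06. Each of these 5 had a camera adjusted p under 0.05 that was lost with an estimated correlation, where the adjusted p was 0.659 for the first 3 and 0.814 for choroid plexus and oxidative phosphorylation. The 4 calls among single genes became 0 without young conditioned library 73, without young naive library 83, and without young naive 81 and old conditioned 61 together. They became 16 without young naive 79 and 2 without old conditioned 65, old naive 67, old naive 69, young conditioned 77 or young naive 81. With the nuclear RNA score as covariate the fry adjusted p of the early list was 0.0532, with 27 of 28 positive and a median of 0.72, and 4 genes passed.

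**Figure D1:**
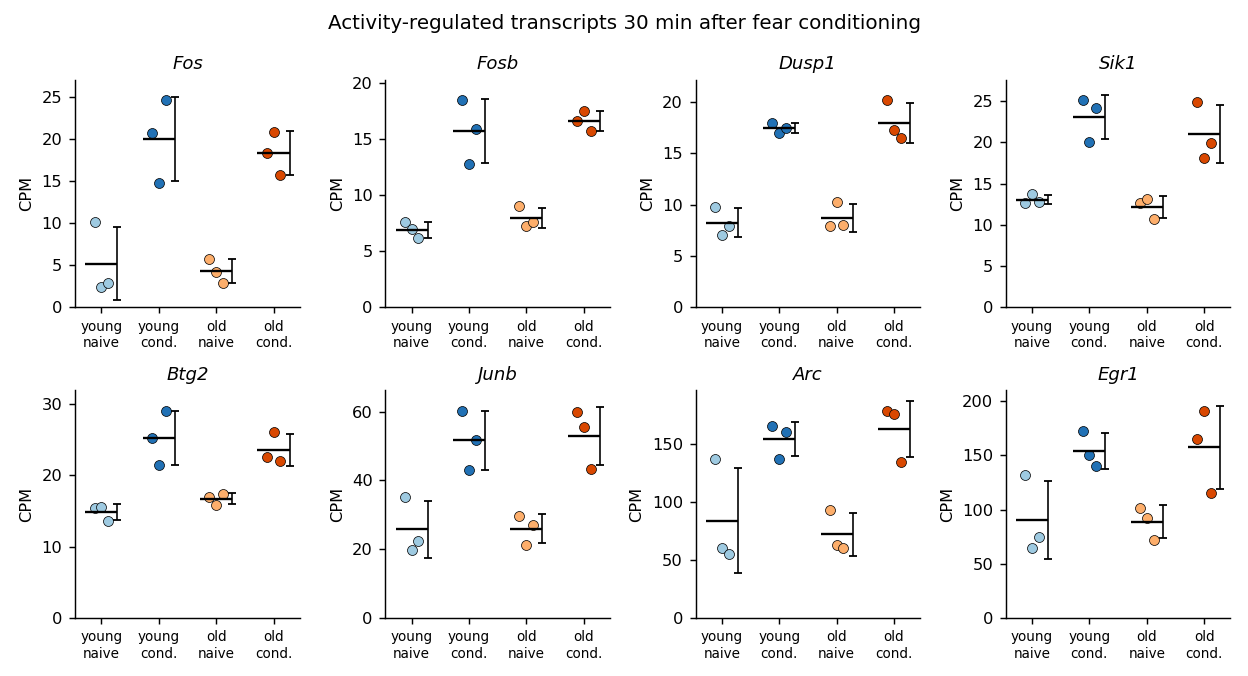
CPM of 8 activity-regulated transcripts in each RNA library; points are libraries, horizontal lines group means and error bars SD (n = 3). Fosb lay at 6.93 and 15.7 CPM in young naive and conditioned mice and at 7.95 and 16.7 CPM in old ones, and 1 young naive library (79) held 10.2 CPM of Fos.

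The same comparison in old mice asks what training changed at 15.5 months. Fosb rose 2.09-fold from 7.95 ± 0.919 to 16.7 ± 0.899 CPM (SD, n = 3 each; log2 1.06, SE 0.143, edgeR adjusted p = 0.0115). Dusp1 rose 2.07-fold from 8.71 ± 1.35 to 18.0 ± 1.94 CPM (log2 1.05, SE 0.137, edgeR adjusted p = 0.0115). Fos stood at 4.28 ± 1.45 in naive and 18.3 ± 2.60 CPM in conditioned mice (log2 2.08, edgeR adjusted p = 0.112). Junb stood at 26.0 ± 4.31 and 52.9 ± 8.51 (log2 1.02, 0.112), and Arc at 71.8 ± 18.5 and 163 ± 24.5 (log2 1.18, 0.309). Sik1 (log2 0.79), Egr1 (0.83), Nr4a1 (0.98) and Npas4 (0.87) did not pass either, and H2afz differed by -0.08. In all, 2 genes passed upward and 0 downward, with 500 higher and 531 lower at an unadjusted p under 0.05, and both called genes separated the libraries fully, as did 12.8% of all genes (10% by chance). DESeq2 called 1 gene higher and 6 lower, none of them these 2: its filter on mean counts set no adjusted p for Fosb, Dusp1, Fos, Junb or Arc. Early activity-regulated genes were again higher as a group, 27 of 28 positive with a median of 0.70, 2 past over all genes and 20 when adjusted over the list alone (camera adjusted p = 1.16e-48, with an estimated correlation 0.0172, fry 0.0352).

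Choroid plexus markers stood lower in the conditioned old libraries without passing the stricter list tests. Their median log2 difference was -2.71, with 15 of 16 lower when adjusted over the list alone and 0 over all genes (camera adjusted p = 9.49e-17, adjusted p = 0.672 with an estimated correlation, fry 0.595), and Ttr stood at 752 CPM in naive and 63.1 CPM in conditioned mice. Effector genes had a median of 0.10, ependymal markers -0.54, thalamus markers 0.23, dentate gyrus markers -0.18, circadian clock genes 0.12 and sex-linked genes -0.24, each with a camera adjusted p under 0.05 and an adjusted p of 0.672 with an estimated correlation. Oligodendrocyte markers had a median of -0.14 (0.713). In the dentate list Dsp stood at 92.3 ± 26.5 and 60.1 ± 5.41 CPM (log2 -0.62, edgeR adjusted p = 0.597). Glucocorticoid-responsive genes had a median of -0.01 and a mean of -0.05, against an upward camera direction, with no call. With the choroid score as covariate no gene passed in old mice, with log2 changes of 0.94 for Fosb and 1.01 for Dusp1. The fry adjusted p of the early list was then 0.109, with 27 of 28 positive and a median of 0.60. The 2 calls became 0 without old conditioned 61 or 63 or old naive 67 or 71, 0 without young naive 81 and old conditioned 61 together, 1 without old conditioned 65 or old naive 69, and 8 without young naive 79.

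Averaged over both ages, 11 transcripts rose with training and 0 fell. Fos rose 4.16-fold (log2 2.06, SE 0.259, edgeR adjusted p = 0.00199), Fosb 2.18-fold (SE 0.103, 6.06e-05), Dusp1 2.10-fold (SE 0.0976, 6.06e-05), Junb 2.03-fold (SE 0.133, 0.00231) and Arc 2.05-fold (SE 0.180, 0.0407), with 6 libraries in each arm. Egr4, a zinc finger transcription factor gene, rose 1.81-fold (SE 0.109, edgeR adjusted p = 0.00199), Sik1 1.75-fold (0.00105) and Btg2 1.54-fold (0.00232). Cyr61, coding for a secreted matricellular protein, rose 2.09-fold (SE 0.163, edgeR adjusted p = 0.0134), Apold1, an early response gene of endothelial cells, 1.88-fold (0.0407) and Tiparp 1.31-fold (0.0378). Egr1 (log2 0.81, edgeR adjusted p = 0.0727), Nr4a1 (0.97, 0.0712) and Npas4 (0.91, 0.203) did not pass. At an unadjusted p under 0.05, 406 genes were higher and 601 lower, and DESeq2 called 15 higher and 4 lower. For 10 of the 11 genes, all but Arc, no conditioned library overlapped a naive one, which 0.216% of 6 against 6 splits give by chance and 0.292% of all genes showed. Both shares are for unselected genes, while the 11 were called on these libraries.

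Early activity-regulated genes made up 10 of these 11 calls, and 24 of the 28 passed when adjusted over the list alone (median 0.72, camera adjusted p = 6.14e-96, with an estimated correlation 0.00163, fry 0.00303). Effector genes had 1 call, Tiparp, and 3 when adjusted over the list alone (median 0.11; adjusted p = 0.115 with an estimated correlation), and glucocorticoid-responsive genes 0 and 6 (median 0.04, 0.353). Myelin and ventricle markers stood lower beside them: oligodendrocyte markers had a median of -0.20 with 0 of 16 positive (camera adjusted p = 4.19e-11, 0.353 with an estimated correlation), precursor markers -0.14 (0.00245, 0.398), ependymal markers -0.63 (2.34e-08, 0.353) and choroid plexus markers -1.56 (9.7e-16, 0.353). CA1 markers had a median of 0.06 (adjusted p = 0.422 with an estimated correlation), dentate markers -0.08 (0.520), clock genes 0.05 (0.422), chromatin regulators -0.02 (0.422) and oxidative phosphorylation genes 0.04 (0.733), all called by camera alone without a covariate. Without young naive 81, the highest in choroid score, and old conditioned 61, the lowest in nuclear RNA score, 7 genes passed, the same number without old naive 71 or young naive 83. 30 passed without young naive 79. With the choroid score as covariate 7 of the 11 passed, all 11 kept their sign, and their median size was 0.83 against 1.02. With that covariate chromatin regulators passed the stricter tests, with 9 of 30 positive and a median of -0.05 (fry adjusted p = 0.00775, with an estimated correlation 0.0432). At single ages fry called them with that covariate, at 0.0289 in young and 0.0375 in old mice, and the call is lost (adjusted p = 0.120 and 0.232 with an estimated correlation). With the nuclear RNA score their fry adjusted p over both ages was 0.331.

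**Figure D2:**
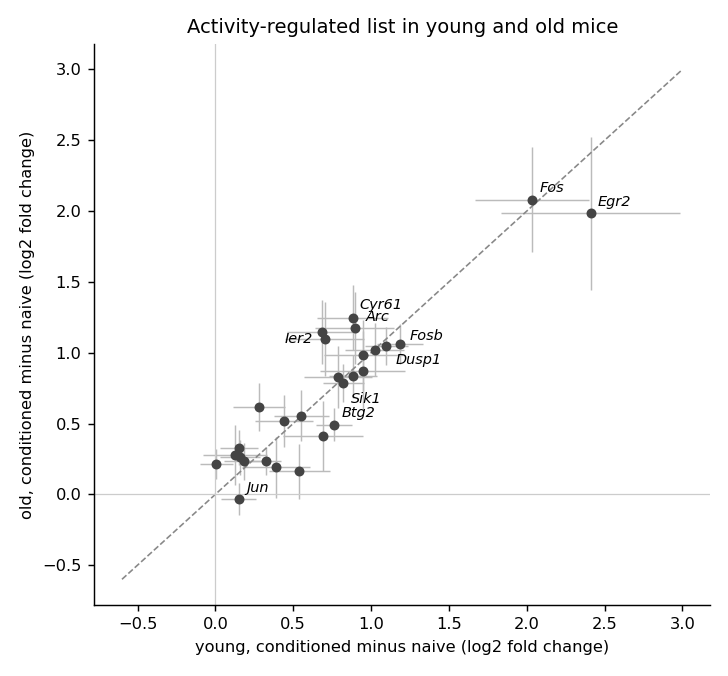
Log2 fold change with training in young (x axis) and old (y axis) mice for the 28 measured early activity-regulated genes; grey bars are standard errors from the edgeR fit of 12 libraries and the dashed line marks equal change. All but Jun lie above 0 at both ages, 27 of 28, with medians of 0.70 at either age.

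Whether training acted differently at the 2 ages was tested by the interaction, the training effect in old minus that in young mice. Fos differed by 0.05 (SE 0.527), Arc by 0.28 (SE 0.358), Junb by -0.00 (SE 0.262) and Egr1 by 0.04 (SE 0.305). The 28 early activity-regulated genes had a median interaction of 0.02 and 0 of them an unadjusted p under 0.05. H2afz differed by -0.25 (SE 0.0896, edgeR adjusted p = 0.680), and Calb1, the calbindin gene of dentate granule cells, by -0.33 (SE 0.105, edgeR adjusted p = 0.680). No gene passed in the edgeR test (smallest adjusted p 0.607), with 518 higher and 519 lower at an unadjusted p under 0.05, and DESeq2 called 1, Kcnt1, a sodium-activated potassium channel gene (log2 0.77 in edgeR, SE 0.138, edgeR adjusted p = 0.607), named after its value was seen. The standard error of 0.527 for Fos leaves room for a difference of about 1 on the log2 scale. Across all 14405 genes the training effects of the 2 ages had a Spearman correlation of 0.0370 and a Pearson correlation of 0.194. Genes are not independent replicates, and the 2 estimates share no library.

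In naive mice, old against young hippocampi show what differed with age without training. C4b, a complement gene, rose 1.88-fold from 36.5 ± 4.70 to 68.8 ± 3.08 CPM (SD, n = 3 each; log2 0.91, SE 0.102, edgeR adjusted p = 0.00208). Ctss, coding for the lysosomal protease cathepsin S, rose 1.43-fold from 39.7 ± 1.38 to 56.8 ± 3.63 CPM (SE 0.0714, edgeR adjusted p = 0.0151). Laptm5, a lysosomal membrane protein gene of blood and microglial cells, rose 1.44-fold from 23.0 ± 1.98 to 33.1 ± 0.900 CPM (SE 0.0902, edgeR adjusted p = 0.0499). Unc13b, coding for a synaptic vesicle priming protein, fell from 64.9 ± 3.26 to 46.6 ± 0.678 CPM (log2 -0.48, SE 0.0738, edgeR adjusted p = 0.0308). Kcnt1 fell from 41.5 ± 3.41 to 27.1 ± 3.04 CPM (log2 -0.61, 0.0330) and the nucleoporin gene Nup188 from 27.3 ± 1.69 to 19.1 ± 0.704 CPM (log2 -0.51, 0.0472). BC061194 (log2 1.61, edgeR adjusted p = 0.0446) and the clustered protocadherin gene Pcdhb9 (0.61, 0.0308) also rose. Pcdhb9 belongs to a family of similar genes whose shared reads were not resolved here. In all 5 genes rose and 3 fell, with 720 higher and 761 lower at an unadjusted p under 0.05, 33 calls by DESeq2, and full separation of the libraries in all 8, as in 13.4% of all genes (10% by chance).

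Microglial markers were higher in old naive mice as a group: all 16 had a positive log2 difference (median 0.28), 2 passed over all genes and 9 when adjusted over the list alone (camera adjusted p = 8e-15, with an estimated correlation 0.0267, fry 0.00269). Neurogenesis genes were lower, with 2 of 19 positive, a median of -0.36, 0 past over all genes and 8 when adjusted over the list alone (camera adjusted p = 2.55e-08, with an estimated correlation 0.0267, fry 0.00931). Dcx, the doublecortin gene of immature neurons, stood at 33.1 ± 3.34 and 22.1 ± 4.02 CPM (log2 -0.58, edgeR adjusted p = 0.201). Other lists called by camera alone, with the adjusted p at an estimated correlation, were inflammaging genes at a median of 0.15 (0.200), collagens and matrix genes -0.32 (0.200), endothelial markers 0.22 (0.200), effector genes 0.11, glucocorticoid-responsive genes 0.17, synapse genes 0.08, oxidative phosphorylation genes 0.09, ribosomal genes 0.12 and nuclear-retained RNAs -0.53 (0.392 for these 6). Thalamus markers (-0.38), dentate markers (0.16) and oligodendrocyte markers (-0.25) had 0.403, and ependymal markers (-0.58) 0.474. The choroid score stood at 3.04 ± 1.40 in old and 3.66 ± 1.55 in young naive libraries, and the nuclear RNA score at 8.29 ± 0.30 and 8.73 ± 0.43 (SD, n = 3). Leaving out 1 library gave 22 calls without young naive 81, 1 without old naive 67, old naive 69, young naive 79 or young naive 83, 2 without old conditioned 63 or young conditioned 75, 3 without old conditioned 61 or old naive 71 and 4 without old conditioned 65. Without young naive 81 and old conditioned 61 there were 32.

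Among conditioned mice the age comparison asks the same question 30 min after training. C4b rose 2.05-fold from 31.0 ± 4.27 to 63.7 ± 3.54 CPM (SD, n = 3 each; log2 1.04, SE 0.103, edgeR adjusted p = 0.000411). BC061194 rose 3.17-fold from 1.41 ± 0.477 to 4.40 ± 0.442 CPM (SE 0.251, edgeR adjusted p = 0.0223). Pcdhb9 (log2 0.81, 0.00202), Pcdhga2 (0.85, 0.0223) and the pseudogene Pisd-ps1 (0.87, 0.0251) rose as well, 3 genes with close relatives in the genome. Gfap, the intermediate filament gene of astrocytes, stood at 258 ± 16.1 in young and 322 ± 29.9 CPM in old mice (log2 0.32, edgeR adjusted p = 0.274). Ctss stood at 38.5 ± 0.878 and 50.0 ± 1.16 CPM (log2 0.38, edgeR adjusted p = 0.105). In this comparison 5 genes rose and 0 fell, with 897 higher and 1029 lower at an unadjusted p under 0.05. DESeq2 called 38 higher and 24 lower, sharing 2 genes. All 5 separated the libraries fully, as did 23.1% of all genes (10% by chance).

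Microglial markers again stood higher in old conditioned mice, 16 of 16 positive with a median of 0.31, 0 past over all genes and 11 when adjusted over the list alone (fry adjusted p = 0.0064; camera adjusted p = 7.68e-11, adjusted p = 0.0758 with an estimated correlation). Neurogenesis genes had a median of -0.30, 2 of 19 positive, 5 lower when adjusted over the list alone and 0 over all genes (fry adjusted p = 0.0210; camera 2.3e-06, 0.0758 with an estimated correlation), and Tubb3, a tubulin gene of that list, had a log2 difference of 0.22. Choroid plexus markers had a median of -2.85, 16 of 16 lower when adjusted over the list alone (camera adjusted p = 4.5e-10, 0.424 with an estimated correlation), and their score was 0.93 ± 0.52 in old and 2.82 ± 2.13 in young conditioned libraries. Y-linked transcripts stood lower as well, Ddx3y at 73.0 ± 1.91 in young and 57.9 ± 9.52 CPM in old mice (log2 -0.33, edgeR adjusted p = 0.236), with 4 of 4 lower when adjusted over the list alone (0.242 with an estimated correlation). Inflammaging genes (0.21), collagens and matrix genes (-0.24), endothelial markers (0.21) and meningeal markers (-0.63) had 0.242 with an estimated correlation, interneuron markers (0.12) 0.448, oligodendrocyte markers (-0.11) 0.743, and ependymal markers (-0.52), oxidative phosphorylation genes (0.07), ribosomal genes (0.08) and nuclear-retained RNAs (-0.36) 0.741. The 5 calls became 2 without old conditioned 61 or 63 or young naive 83, 3 without old conditioned 65, young conditioned 73, 75 or 77, and 2 without young naive 81 and old conditioned 61. With the choroid score as covariate 3 genes passed, and BC061194 (log2 1.44) and Pisd-ps1 (0.74) no longer did.

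Averaged over naive and conditioned mice, 21 transcripts rose and 33 fell with age, and complement, microglial and progenitor genes stood among them. C4b rose 1.96-fold (log2 0.97, SE 0.0726, edgeR adjusted p = 6.66e-06, n = 6 libraries per age). Ctss rose 1.36-fold (SE 0.0506, 0.000582), Laptm5 1.37-fold (SE 0.0636, 0.00394), the complement gene C1qb 1.34-fold (SE 0.0812, 0.0382) and the microglial membrane protein gene Tmem119 1.32-fold (SE 0.0826, 0.0485). Zc3hav1, coding for a zinc finger antiviral protein, rose 1.91-fold (SE 0.124, edgeR adjusted p = 0.00266) and Aldoc, an astrocytic aldolase gene, 1.19-fold (SE 0.0443, 0.0230). Gfap had a log2 difference of 0.34 (edgeR adjusted p = 0.0715). Dcx fell by 0.59 on the log2 scale (SE 0.10, edgeR adjusted p = 0.0208). The proliferation genes Top2a and Mki67 fell by 1.37 (0.0286) and 1.21 (0.0382), from levels of 1.93 ± 0.255 and 2.69 ± 0.992 CPM in young naive mice. Tnc, the gene of the matrix protein tenascin C, fell by 0.90 (SE 0.133, edgeR adjusted p = 0.00728). The collagen genes Col3a1 and Col1a2 fell by 1.32 (0.0390) and 0.81 (0.0454). Among the other named falls were Coch (log2 -1.08), 1700123O21Rik (-0.99), Gm3414 (-0.69), Rad1 (-0.54), Ulk4 (-0.45), Cxadr (-0.44), Rdh10 (-0.41) and Cep162 (-0.38), and among the rises BC061194 (1.63), Pcdhga2 (0.77), Pisd-ps1 (0.72), Pcdhb9 (0.71), Pcdhb2 (0.63) and Pcdhb3 (0.56). At an unadjusted p under 0.05, 1056 genes were higher and 1335 lower, and DESeq2 called 108 higher and 128 lower. Of the 54 genes 40 separated all old from all young libraries, against 0.216% by chance and 1.40% of all genes. The 54 were called on these same libraries, so this is no further support for them.

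**Figure D3:**
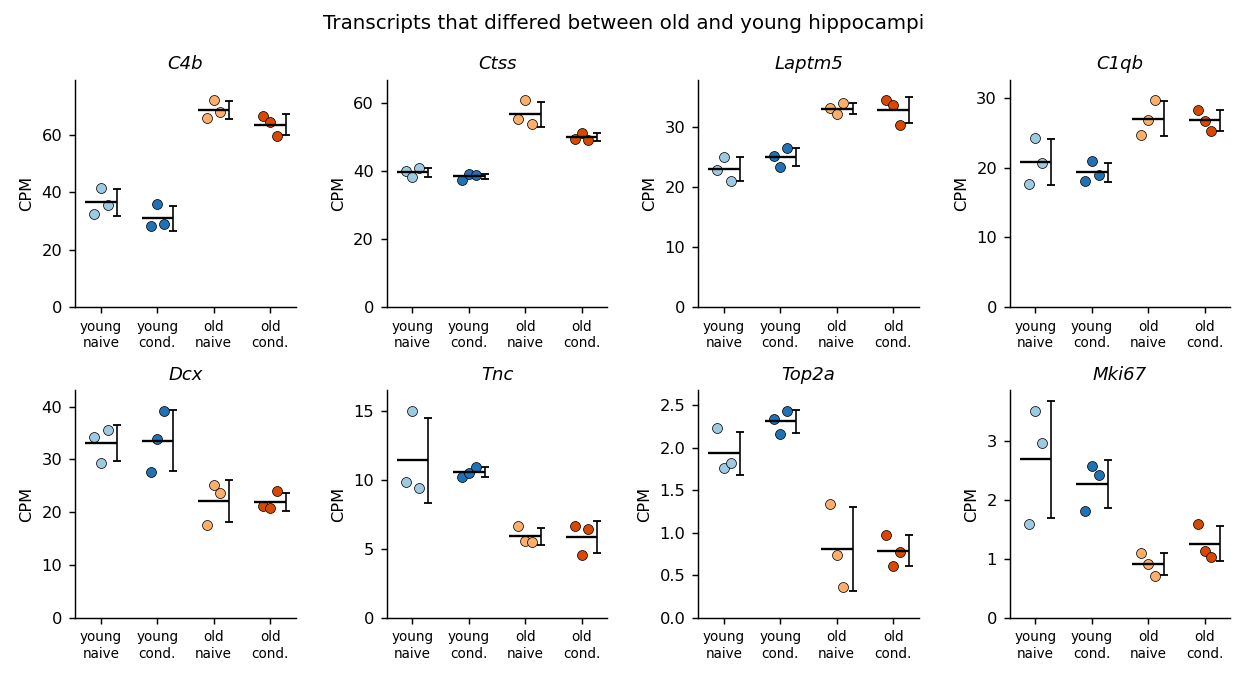
CPM of 8 transcripts that passed in the age comparison over both conditions, in each RNA library; points are libraries, horizontal lines group means and error bars SD (n = 3). C4b lay at 36.5 and 31.0 CPM in the young groups and at 68.8 and 63.7 CPM in the old ones, and Dcx at 33.1 and 33.5 against 22.1 and 22.0 CPM.

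Among the lists, all 16 microglial markers were higher with age (median 0.29), 4 past over all genes and 12 when adjusted over the list alone (camera adjusted p = 8.35e-20, with an estimated correlation 0.0103, fry 0.000289). Their mean log2 CPM was 4.46 ± 0.06 in old and 4.16 ± 0.05 in young libraries (SD, n = 6 each; exact permutation p = 0.00216, adjusted 0.0779 over 36 comparisons). Of 19 neurogenesis genes 17 were lower, 5 past over all genes and 11 when adjusted over the list alone (median -0.25, mean -0.65; camera adjusted p = 4.64e-11, with an estimated correlation 0.0105, fry 0.0011). Collagens and matrix genes had a median of -0.19 with 2 and 6 past (fry adjusted p = 0.0199, adjusted p = 0.0992 with an estimated correlation), inflammaging genes 0.21 with 1 and 2 past (fry 0.026, 0.0936), and endothelial markers 0.18 with 0 and 5 past (fry 0.0199, 0.0936). Choroid plexus markers stood lower beside these lists, at a median of -1.92 with 16 of 16 past when adjusted over the list alone (0.362 with an estimated correlation), and so did nuclear-retained RNAs at -0.43 with 6 of 7 (0.347). With the choroid score as covariate 264 genes passed, 48 of the 54 among them. With the nuclear RNA score 22 passed, 15 of the 54 among them, and the median size of the 54 was 0.42 against 0.50. Fry kept both lists with either score, microglial at 0.00125 and 0.00214 and neurogenesis at 0.00467 and 0.00214. The 54 calls became 391 without young naive 81, 13 without old conditioned 61 or 63, 14 without young naive 83, 15 without young conditioned 75 or 77, 18 without old naive 67, 25 without old naive 69, 34 without young conditioned 73, and 90 without young naive 81 and old conditioned 61.

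Single genes of the remaining lists seldom passed. Oligodendrocyte markers had a median of -0.17 with 5 lower when adjusted over the list alone (adjusted p = 0.454 with an estimated correlation), astrocyte markers 0.03 with 1 call, Aldoc (0.588), meningeal markers -0.57 (0.311), ependymal markers -0.56 (0.377), interneuron markers 0.09 (0.347), synapse genes 0.08 (0.362) and sex-linked genes -0.27 (0.347). 69 of 77 oxidative phosphorylation genes (median 0.08) and 78 of 82 ribosomal genes (0.09) were positive (0.362 for both). Oligodendrocyte precursor markers (-0.10), effector genes (0.06), glucocorticoid-responsive genes (0.06), early activity-regulated genes (0.03), interferon-response genes (0.02), mural cell markers (-0.13), clock genes (0.05), heat shock genes (-0.05), chromatin regulators (-0.05) and H2A.Z machinery (-0.01, mean 0.01) had no call by camera, and neither did markers of CA1 (0.07), CA3 (-0.01), the dentate gyrus (0.08), cortex (0.00), striatum (-0.05) and thalamus (-0.09). With the choroid score as covariate fry called chromatin regulators (median -0.06, fry adjusted p = 0.00309, adjusted p = 0.158 with an estimated correlation) and inflammaging genes (0.35, 0.00307, 0.0172). With the nuclear RNA score it called meningeal markers (-0.57, 0.0254, 0.0676). Too few of the blood markers were measured for a test. Across the 14405 genes the age effects in naive and conditioned mice had a Spearman correlation of 0.259 and a Pearson correlation of 0.371.

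H2A.Z replaces the ordinary histone H2A in nucleosomes, often beside transcription start sites. The authors' deposited table lists 20213 peaks of H2A.Z on mm10, with a median width of 887 bp, and gives group means, folds and FDR values without single libraries. Of these peaks, 12204 (60.4%) in the authors' deposited table lie within 1 kb of the transcription start site of 11646 genes. By the distances in the authors' deposited table, 76.3% of the peaks overlap a region of H3K4me1, 72.4% of H3K4me3, 50.7% of H3K27ac and 33.1% of H3K27me3, marks of active or repressed promoters and enhancers whose origin the table does not state. The groups named T in the authors' deposited table are taken to be the conditioned mice, since the groups named N are the naive ones, and the read depth behind its values is unknown.

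In young mice H2A.Z was lower after training at 2660 peaks and higher at 22 (FDR 0.05 in the authors' deposited table). The median log2 fold over all peaks of the authors' deposited table was -0.57 (0.675-fold), and 81.1% of peaks had a negative fold. By the authors' deposited table, 10360 peaks were called in all 3 young conditioned libraries against 10085 in young naive ones, and 1825 against 1902 in none of them. In old mice 9572 peaks of the authors' deposited table were called in all 3 conditioned against 10885 in all 3 naive libraries, and 613 against 390 in none. In the authors' deposited table the peak at the Fos promoter (chromosome 12, 85473573 to 85475096) had a log2 fold of -3.49 (FDR 1.95e-07) and the peak at Fosb (chromosome 7, 19309379 to 19310695) -1.38 (FDR 0.0218). The promoter of H2afz itself (chromosome 3, 137863728 to 137865845) had -1.13 (FDR 0.0449) and that of Nr4a2, an early nuclear receptor gene, -1.64 (FDR 0.00232) in the authors' deposited table. Promoters of Arc (0.12, FDR 0.881), Egr1 (-0.62, FDR 0.343), Dusp1 (0.39, FDR 0.656), Npas4 (-0.97, FDR 0.260), Nr4a1 (-0.16, FDR 0.893) and H2afv (-0.20, FDR 0.829) did not pass in the authors' deposited table. The 5 lowest promoter folds of the authors' deposited table were at Wdpcp (-6.69, FDR 4.49e-13), Tmub2 (-6.65), Spdl1 (-6.59), Mpp2 (-6.47) and Ube2l6 (-6.30), and both promoter rises were at Msh4 (2.47, FDR 0.0177) and Ski (1.55, FDR 0.0180). Of the 20 lowest promoter folds in the authors' deposited table, 16 had the conditioned group at its lowest possible level, so that their size depends on that floor, against 81 of all 2660.

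In old mice the authors' deposited table has 2150 peaks lower and 8 higher after training, with a median log2 fold of -0.93 (0.524-fold) and 87.3% of peaks negative. Promoters of Egr2 (-2.36, FDR 0.0159), Nr4a2 (-1.68, FDR 0.0342), Sik1 (-1.28, FDR 0.0200) and Klf10 (-0.97, FDR 0.0206), all early activity-regulated genes, passed in the authors' deposited table. Of 26 promoters of such genes 4 passed as lower (15.4%), against 16.6% of all promoters in the authors' deposited table. Promoters of Fos (-1.49, FDR 0.380), Fosb (-1.28, FDR 0.297), H2afz (-1.21, FDR 0.0509), Egr1 (-0.88, FDR 0.0720), Dusp1 (-0.84, FDR 0.0861), H2afv (-1.22, FDR 0.104) and Arc (-0.62, FDR 0.410) did not pass in old mice in the authors' deposited table. The lowest promoter folds in the authors' deposited table were at Peli3 (-5.01, FDR 0.00747), Zfp442 (-4.62, FDR 0.0136), Il1r2 (-4.14, FDR 0.0150), Stard13 (-4.03, FDR 0.0309) and the MHC class II gene H2-Ab1 (-3.91, FDR 0.0432). At Peli3 and Zfp442 the conditioned group of the authors' deposited table was at its lowest possible level, so that the size of these 2 folds depends on that floor. All 8 higher peaks of the authors' deposited table had the naive group at its lowest level and 7 lie in regions of low mappability. Of these, 6 are higher at both ages in the authors' deposited table, 3 of them near Lrrc4c. At an FDR of 0.01 in the authors' deposited table, 1317 peaks pass in young and 357 in old mice.

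Between the ages, the fold of a peak in young and in old mice in the authors' deposited table had a Spearman correlation of 0.587 across peaks, and 0.253 to 0.736 within 10 bins of equal size by H2A.Z level. Of the peaks called lower in young mice 99.7% had a negative fold in old mice, and 97.4% the other way round, in the authors' deposited table. In all, 160 peaks of the authors' deposited table passed as lower at both ages, where 283 would by chance (odds ratio 0.501, but 1.82 within these bins). The calls sat at weaker peaks in young mice (median log2 level 5.44) than in old mice (7.49) in the authors' deposited table. In the bin of highest level 1.53% of peaks passed as lower in young and 47.3% in old mice, with median folds of -0.36 and -0.95, in the authors' deposited table. The authors' deposited table has no test of the difference between the ages, and none was run. In the authors' deposited table the fold was lower in old mice at 68.2% of peaks.

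**Figure D4:**
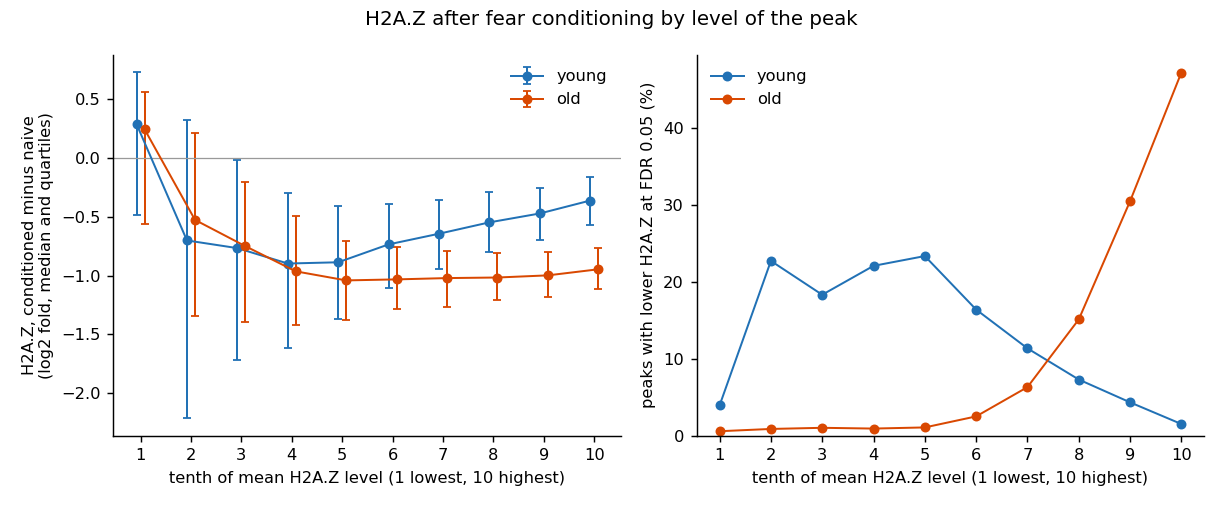
H2A.Z after training in 10 bins by mean H2A.Z level, from the authors' deposited table of 20213 peaks; left, median log2 fold with quartiles, right, percent of peaks called lower at FDR 0.05. Calls reach 23.4% in bin 5 in young mice and 47.3% in bin 10, the highest, in old mice.

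With age alone no peak passed in the authors' deposited table. In naive mice 2390 peaks were higher and 52 lower in old mice at an unadjusted p under 0.05 in the authors' deposited table, with a median log2 fold of 0.33 and a smallest FDR of 0.209. The median fold was 0.07 in the lowest bin of level, -0.04 in the next and 0.65 in the highest, in the authors' deposited table. In conditioned mice the authors' deposited table has 101 peaks higher and 11 lower at an unadjusted p under 0.05, a median of 0.09 and a smallest FDR of 1.00. Promoters of H2afv (0.99, FDR 0.346), Arc (0.79, FDR 0.537), H2afz (0.66, FDR 0.469), Egr1 (0.34, FDR 0.821), Kcnt1 (0.85, FDR 0.495) and Unc13b (0.67, FDR 0.495) had positive folds with age in naive mice and Fos (-0.18, FDR 0.996) a negative one, in the authors' deposited table. In conditioned mice the promoter of Fos had 1.82 and that of Nr4a1 -1.02 (FDR 1.00 for both) in the authors' deposited table.

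The series set H2A.Z beside expression, and both were joined here through promoters. Of 14405 expressed genes 10817 (75.1%) had a peak of the authors' deposited table within 1 kb, from 37.2% in the lowest of 10 bins of expression to 90% in bin 9 and 89.2% in bin 10. Genes with higher expression also had higher H2A.Z levels in the authors' deposited table: across genes the Spearman correlation was 0.215 in young naive, 0.309 in young conditioned, 0.290 in old naive and 0.373 in old conditioned mice. Each of these 4 correlations with the authors' deposited table had a permutation p of 1e-05, the smallest that 100000 permutations can give, and genes are not independent replicates. With genes at a mean of at least 5 CPM the correlation with the authors' deposited table was 0.111 in young naive and 0.186 in old naive mice. Median falls of promoter H2A.Z after training in the authors' deposited table ran from -0.82 in the lowest to -0.41 in the highest bin of expression in young mice, and from -1.15 to -0.84 in old mice. The median H2A.Z level of these promoters in the authors' deposited table was 5.84 in the lowest and 7.05 in the highest bin. Falls were not compared at like level, so a relation to expression cannot be told apart from 1 to level.

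**Figure D5:**
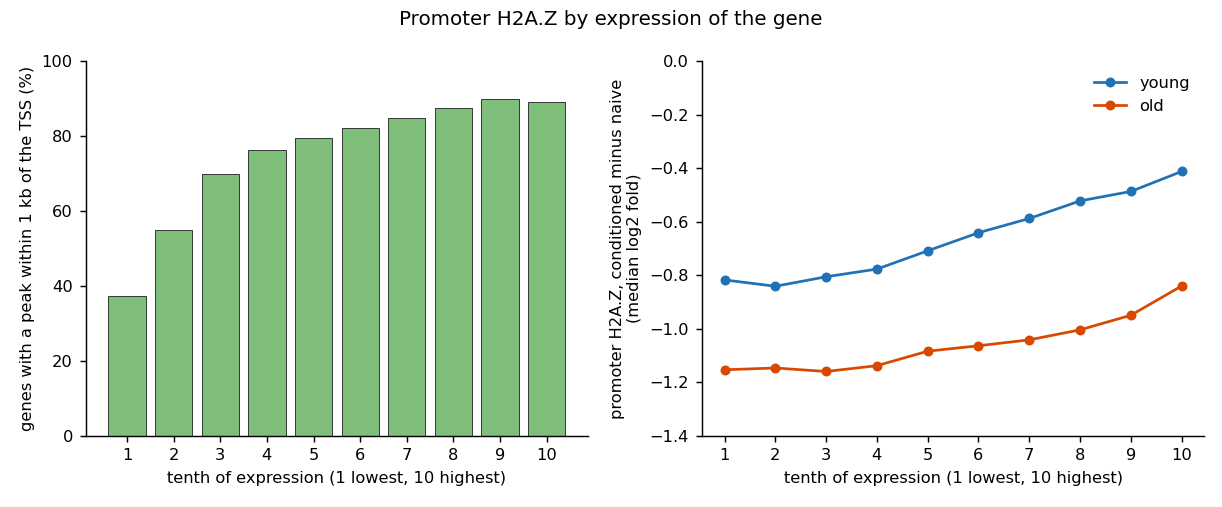
Promoter H2A.Z in 10 bins of mean RNA expression, from the authors' deposited table; left, percent of genes with a peak within 1 kb of the start site, right, median log2 fold of those peaks after training. The percentage goes from 37.2% to 89.2%, and the median fold lies below 0 in every bin at both ages.

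Across genes, changes of expression and of promoter H2A.Z had weak positive correlations, and the correlation for training in young mice did not pass. Fosb, which rose by 1.19 on the log2 scale in young mice, and Fos, which had 2.03 without passing, had H2A.Z folds of -1.38 and -3.49 in the authors' deposited table, while Arc at 0.90 and Dusp1 at 1.1 had 0.12 and 0.39. Egr2, an early transcription factor gene, had H2A.Z folds of -1.72 in young (FDR 0.130) and -2.36 in old mice in the authors' deposited table. Across 10817 genes the Spearman correlation of the log2 changes with those of the authors' deposited table was 0.0163 for training in young mice (permutation p = 0.0890) and 0.0279 in old mice (p = 0.00364, Benjamini-Hochberg 0.00485 over 4 correlations). For age it was 0.0711 in naive and 0.0671 in conditioned mice with the authors' deposited table (permutation p = 1e-05 each, the smallest they can give, adjusted 2e-05). The positive sign of all 4 is opposite to the direction at Fosb and Fos, and genes are not independent replicates. With genes at a mean of at least 5 CPM the correlation with the authors' deposited table was 0.00102 for training in young mice (permutation p = 0.921) and 0.0458 for age in naive mice (permutation p = 2e-05). Of the 4 genes called in young mice 1, Fosb, also had lower promoter H2A.Z in the authors' deposited table, where 0.576 would by chance (Fisher's exact p = 0.463), and of the 2 in old mice 0, where 0.349 would. None of the 29 gene lists tested passed for its share of lower peaks against all promoters in the authors' deposited table (Fisher's exact test, smallest adjusted p 0.762 in young and 0.389 in old mice). Early activity-regulated genes had 4 of 26 promoters lower at each age in the authors' deposited table.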

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

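All tests in this part were chosen after the results were seen, except the list tests and the comparisons, which were planned.

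In the authors' deposited table H2A.Z calls after training were lower for 99.2% in young and 99.6% in old mice, with median folds over all peaks of -0.57 and -0.93. A single factor on the values as deposited is argued against as the only source in young mice. There the median folds of bins 5 and 10 of 10 by level differed by 0.52. In old mice, where they differed by 0.0945, it is not argued against. For old mice this covers the stronger peaks only, as bins 1 to 3 had median folds of 0.24, -0.53 and -0.75. Lower enrichment over background in the conditioned libraries as the only source predicts a fall that grows with level and then stays. That holds only where background reads remain in the values. The top bin had -0.36 in young mice, smaller than the -0.89 of bin 5, so the prediction is not met there. In old mice it had -0.95 against -1.04 in bin 5, so the prediction is met. Whether input was subtracted is not given, and subtraction could make weak peaks fall more. Of 483 peaks at the lowest young conditioned level, 95 were called in all 3 libraries. The young values therefore do not argue against lower enrichment, nor against 1 factor on the reads before any subtraction. A common factor as part of the fall at either age and 1 factor on the reads before any subtraction remain open. So do lower enrichment over background and an effect of training. The table has no values per library and no spiked reference.

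H2A.Z calls sat at weak peaks in young and at strong peaks in old mice. At weak peaks the implied standard error in old mice was 1.40 times that in young mice, with like median folds of -0.84 in young and -0.89 in old mice. That error comes from the same p-values that make the calls, so it is no separate test of a larger spread between old libraries. Lower quartiles of the folds were -2.21 in young and -1.34 in old mice in bin 2, and -1.37 and -1.38 in bin 5. A larger spread at weak peaks thus stays open beside larger falls of some peaks in young mice. For bins 8 and 9 of 10 by level the ratio was 1.06, so the implied error was not smaller in old mice there. Median folds in these bins were -0.51 in young and -1.01 in old mice. Drawn from the same p-values, the ratio is no separate test of a smaller spread at strong peaks either. For bin 10, which holds 956 of the 1879 strong-peak calls in old mice, the ratio was 0.80 while the median folds also differed, at -0.36 and -0.95, so a smaller spread there stays open beside a larger fall. The difference of -0.53 between the ages' median folds over bins 8 to 10 was not tested.

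Microglial genes were higher and progenitor genes lower in old mice. Choroid plexus carried along is argued against as the whole cause, since both lists passed with that score as covariate (larger fry adjusted p 0.00467), and so is a different share of nuclear RNA (0.00214). A lower share of neurons would raise the markers of all other cells, while oligodendrocyte markers had a median of -0.17. That list did not pass the stricter tests (camera with an estimated correlation, adjusted p = 0.454, fry 0.273), so a lower share of neurons stays open. With the nuclear RNA score, however, 15 of 54 single genes passed, as the median size went from 0.50 to 0.42 and the standard error from 0.0837 to 0.0924; with both scores the lists had fry adjusted p-values of 0.0226 and 0.0385. Age and any batch that followed it remain open, as the labels give no batches.

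Training effects of 8 gene lists differed between the ages by camera, and none by fry or with an estimated correlation. The median difference, old minus young, was -0.13 for effector genes (camera adjusted p = 0.0234, adjusted p = 0.869 with an estimated correlation). It was -0.23 for glucocorticoid-responsive genes (0.00249, 0.869) and -2.30 for choroid plexus markers (6.69e-05, 0.916). Region markers had 0.53 for thalamus (0.00141, 0.869), -0.18 for CA3 (0.0234, 0.869) and -0.19 for the dentate gyrus (0.0051, 0.869). Ribosomal genes had -0.043 (0.0289, 0.971) and sex-linked genes -0.32 (0.0089, 0.869).

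Other splits of the same libraries were fitted in the same way, and the counts out of 10 below include the real split. For training in young mice 2 of the 10 splits gave as many genes; the real split called 4 and the highest other 137, too few splits for a share under 0.05. That split set young conditioned 73 and 77 and young naive 79 against the rest, with a choroid score difference of 2.75, and points to a structure of the samples. For training in old mice 1 of the 10 splits, the real one itself, gave as many (real 2, highest other 0). The same held for age in conditioned mice (5, 0). For age in naive mice 2 of the 10 gave as many (8, 15). These are again too few splits for a share under 0.05. For the interaction the real split called 0, a count that all of the 100 splits reach by construction, so they test nothing there. The highest other called 48. For training over both ages 5 of the 100 splits gave as many, so chance is not excluded. The real split called 11 and the highest other 177, with a choroid score difference of 2.43. That other split set old conditioned 61, 63 and 65, young conditioned 73 and 77 and young naive 79 against the rest. It keeps most of the training grouping, so its calls can hold training effects beside a structure of the samples. For age over both conditions 4 of the 100 gave as many, a share under 0.05. The real split called 54, and the highest other, 244, differed by 0.51 in the nuclear RNA score. That highest other split set old conditioned 61, 63 and 65, old naive 67 and 69 and young naive 81 against the rest. It keeps most of the age grouping, so its calls can hold age effects beside a structure of the samples.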

How the results depend on the processing

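The fits with choroid or nuclear RNA scores as covariates, without young naive 81 and old conditioned 61 together, without low-mappability peaks and without peaks at a group's lowest level were chosen after seeing the data; the others were planned. No paired analysis was possible because the title numbers of the RNA libraries are unique and the H2A.Z table has no values per library.

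DESeq2 called 8 genes for training in young mice, 7 in old mice, 33 for age in naive and 62 in conditioned mice, 1 for the interaction, 19 for training and 236 for age over both. Without a filter there were 8, 9 and 26 for the first 3 of these, 18 for training and 192 for age over both. Upper-quartile factors gave 2 for training in young mice and limma-voom 5 for age in naive mice. With only the 2 groups compared there were 0 for training in young mice, 8 in old mice and 1 for age in naive mice; that fit has fewer samples. With the choroid score as covariate there were 7 and 0 for training in young and old mice, 18 and 3 for age in naive and conditioned mice, and 264 for age over both. The nuclear RNA score gave 22 for age over both. Both scores gave 0 for training in old mice, 4 and 1 for age in naive and conditioned mice, and 7 and 6 for training and age over both. Without young naive 81 and old conditioned 61 there were 0 and 0 for training in young and old mice, 32 and 2 for age in naive and conditioned mice, and 7 and 90 over both. The cause of these differences was not tested.

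Leaving out 1 library gave 0 to 16 genes for training in young mice, 0 to 8 in old mice, 1 to 22 for age in naive mice, 2 to 7 in conditioned mice, 7 to 30 for training over both ages and 13 to 391 for age over both conditions. Young naive 79 left out gave the highest training counts of 16, 8 and 30, and young naive 81 left out the highest age counts of 22 and 391. The interaction had 0 calls in each of these fits.

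Gene lists called by camera at the preset correlation numbered 8, 9, 15, 14, 8, 12 and 16 for training in young and old mice, age in naive and conditioned mice, the interaction, and training and age over both. With the estimated correlation they numbered 1, 1, 2, 0, 0, 1 and 2, and by fry 1, 1, 2, 2, 0, 1 and 5; the preset correlation lies below most of the estimated ones.

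Of 552 comparisons over 49 results for single named genes, 427 kept their direction and their side of the threshold, 125 kept their direction but no longer passed, and 0 reversed. Both scores as covariates ended 29 of them, and DESeq2 5, by setting no adjusted p. The fit at a mean of at least 5 CPM gave 42 of the 49 the same and 1 weaker; the others, BC061194 among them, were not in it. Of the fits with 1 library left out, only those with the lowest and the highest log2 change of a gene entered these counts. Under every setting so counted 14 passed: C4b in all 3 age comparisons, BC061194, Ctss, Pcdhb9, Pcdhga2 and Tnc for age over both conditions, and Dusp1, Egr4, Fos, Fosb, Junb and Sik1 for training over both ages.

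H2A.Z calls after training in the authors' deposited table went from 2682 to 1317 in young and from 2158 to 357 in old mice at an FDR of 0.01, a stricter threshold by construction. With the peaks of lowest mean level left out they were 1955 and 2113, and the age comparisons had 0 calls under each setting. The correlation of expression and H2A.Z level was 0.111 in young naive and 0.186 in old naive mice with genes of at least 5 CPM, which leaves fewer genes; the correlation of changes there was 0.00102 for training in young mice and 0.0458 for age in naive mice.

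Not run were per-library median centring, a larger pseudocount and leaving out single immunoprecipitated libraries, since the H2A.Z table gives no values per library. H2A.Z training by age, training over both ages and age over both conditions were not tested either, by the plan for such a table. On simulated data at this depth and size, 70 of 100 genes changed 1.5-fold and 91 of 100 changed 2-fold were called, with 12 false among 173 calls. Changes under 1.5-fold are thus partly out of reach. In the real young libraries Fosb, Dusp1, Sik1 and Btg2 passed at log2 changes of 0.76 to 1.19. Fos at 2.03 and Arc at 0.90 did not pass there, so the simulated shares cannot be taken as the shares found in the real libraries.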

Other observations

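The tests of this part were chosen after the results were seen.

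Shares of H2A.Z calls are given here by histone mark, without a comparison at like level of H2A.Z or a test of the difference. In the authors' deposited table the median log2 level was 6.59 at peaks with H3K4me3 and 4.04 at peaks without it. Peaks that overlap H3K4me3, a promoter mark, were called lower after training in 15.6% of cases in young and 14.5% in old mice, against 6.76% and 0.574% of peaks without it, in the authors' deposited table. Distal peaks with H3K4me1 and H3K27ac, marks of active enhancers, were called lower in 20.7% and 6.83% of 1948 cases in the authors' deposited table. On the X chromosome 12.1% and 1.62% of 494 peaks were called lower, with median folds of -0.77 and -1.02, in the authors' deposited table.

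Young naive library 79 held more of several early transcripts than the other 2 young naive libraries: 131 CPM of Egr1 against 64.4 and 74.4, 68.9 CPM of Nr4a1 against 25.6 and 28.7, and 35.2 CPM of Junb against 19.6 and 22.4.

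A hypothesis was that promoters of early activity-regulated genes lose H2A.Z after training more often than other promoters. In the authors' deposited table the odds ratio was 1.09 in young mice (95% confidence interval 0.272 to 3.20, Fisher's exact test) and 0.916 in old mice (0.229 to 2.70). With 26 such promoters the intervals span both directions, and the hypothesis stays open.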
